A study of Saccharomyces cerevisiae with 56 samples.

How the data were processed

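The samples were 56 sequencing libraries from yeast (strain BY4742) that carried variants of the third PDZ domain of PSD-95 in 4 constructs: the domain alone (PDZ3), the domain with an extension the labels name N, with one named C, and with both (NC). Each construct was put through 2 growth competitions in methotrexate, 1 that reads the abundance of the domain (abundancePCA) and 1 that reads its binding to a partner (bindingPCA). Each construct and assay had 3 input libraries, 3 output libraries and 1 library of the wild type. Per the labels, the competitions ran for about 5 generations at 30 °C in 400 mL. The labels give a starting optical density of 0.05 and, apart from it, an input density of 1.6. The sequences of the extensions and the ligand are not given in the sources used here.

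The deposited table gives, for each variant in each construct and assay, a score that the authors call fitness, its standard error, and a growth rate that was an exact straight line of that score. In all it held 384696 entries. The authors merged the cultures into 1 value: counts, per-culture values and read depths are not in the table, so the depth is unknown and no counting interval can be given. The submitters' processing notes name cutadapt and FastQC without versions. The score is relative to the wild type, which lay near 0, and its log base is not stated. 8 entries marked as wild type held a placeholder error and were left out. The wild type of NC was not listed apart from that placeholder, so its error was taken from the error of its growth rate, with the ratio between both kinds of error in the same set. The last 2 letters of each sequence mark the construct and were not read as substitutions. Positions carry the numbers of full-length PSD-95, and the block covers 66 residues, from R312 to I377.

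The analysis was fixed before the data were examined: the tests and their order of preference, the lists of positions, the rule for the names to print and the alternatives in the closing section, apart from those said there to be added. The preferred tests needed counts or per-culture values. In their absence the substitute fixed for that case was used, a two-sided normal test of a score, or of a difference between scores, over the authors' error, with Benjamini-Hochberg adjustment and a threshold of 0.05. These tests rest on the authors' error. No paired analysis was possible because per-culture values are not in the table. For the same reason neither a competitive gene-set test nor the leaving out of single cultures could be run. Synonymous variants give a check on the error: among them 31.2%, 17.1%, 7.34% and 6.25% lay past the threshold in abundance (PDZ3, N, C and NC, in this order) and 4.81%, 6.69%, 16.5% and 11.3% in binding. Most of these lay above the wild type (45 of 173 above and 9 below in the abundance of PDZ3, 38 of 254 above and 4 below in the binding of C). Counts of substitutions above the wild type are therefore less certain than those below it. Nonsense variants from G345 on spread more than their errors, by factors of 3.28 (PDZ3), 3.24 (N), 1.26 (C) and 1.63 (NC) in abundance. In binding these were 1, 1.70, 2.88 and 1.91, with 1 as the lowest value allowed. Errors multiplied by 2 are milder than the factors of PDZ3 and N in abundance and of C in binding. The printed standard errors are not widened by these factors.

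Single substitutions were compared between constructs on the unscaled score when they had been measured in all 4 constructs of the assay. A unit of that score did not stand for the same change of growth rate in all sets. In abundance it was 0.116 (PDZ3), 0.127 (N), 0.112 (C) and 0.127 (NC). In binding it was 0.102, 0.109, 0.170 and 0.168. Values per position, list and substitution class were put on a scale on which the wild type is 0 and the median single nonsense variant of the same construct and assay is -1, since the competitions differ in growth range. A position's value is the mean over its missense substitutions measured in all 4 constructs of an assay, or in all 8 sets where binding is set against abundance. Its error combines those of the substitutions, of the wild type and of the scale, the last from 2000 bootstrap draws of the nonsense variants. All positions of a set share its wild type and scale, so the tests of a contrast are not independent. In the closing section, the errors of differences between nonsense variants and between slopes come from 2000 bootstrap draws of the variants or positions, and those of double substitutions from 1000 draws of the substitutions. Positions needed at least 10 such substitutions, which left 60, with 16 to 19 each. G319, G351, G356 and N363 had no single substitutions in the table, and S320 and D332 had too few. The contrasts were N, C and NC against PDZ3 in each assay, binding against abundance in each construct, the difference of that between constructs, and the difference between the effect of C with N and without N. All contrasts against PDZ3 use the same PDZ3 values, so likeness among them was not tested. Adjustment was over the 60 positions of a contrast.

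The lists were the carboxylate-binding loop, the peptide-contacting sites, strands 1 to 4, helix 1, helix 2, strand 6, the positions nearest the N-terminal end (R312 to G324) and the C-terminal end of the block (its last 13 tested positions), and classes by wild-type residue (aliphatic or aromatic, charged, polar, glycine or proline). Their limits are recalled from the known structure and approximate. Strand 6 has no member in the block, and L379 and K380 lie outside it, so these were not analysed here, and 14 lists were left. The median difference of a list was ranked among 10000 random lists of the same size, matched on mean effect, and a percentile below 2.5 or above 97.5 was read as a call. No adjustment was made over lists, which overlap. Correlations between contrasts were tested with 100000 permutations of the 60 positions, in a family of 4.

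The names printed were the 6 positions with the largest differences of each sign in a contrast, the 4 substitutions of each sign, the 6 lowest and 4 highest positions of a construct, the 8 lowest and 3 highest positions of binding against abundance, the 4 of each sign for its difference between constructs, the members of lists with a call, and H372, G322, L323, F325, I327, G330, S339, A347, L353, V362 and A376. The part of the rule that asks for separation of all 3 cultures could not be applied. Non-additive positions had no limit of their own in the rule, and the 4 of each sign are given.

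The steps were tested on simulated data with the authors' errors, in which 200 substitutions and 12 positions were changed. Over the 6 contrasts between constructs, a change of 0.2 was recovered at 60.4% to 91.8% of substitutions and a change of 0.4 at 84% to 100%, of 1128 to 1137 tested. At positions (60 tested) a change of 0.1 was recovered in 0% to 100% of cases and one of 0.2 in 100%. Unchanged substitutions were called in 0.422% to 0.856% of cases. The simulated noise was drawn from the authors' errors, so these rates hold only if those errors are right. The share of synonymous variants past the threshold puts that in doubt. In other draws the positions of strand 1 were shifted by 0.2, and 7.69% to 15.4% of the other lists lay outside the central 95%. Some of those share positions with strand 1, such as the list nearest the N-terminal end, so this is not a rate for unchanged lists. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The alternatives were errors multiplied by 2, variants with an error above the median left out, no scaling, other reference variants for the scale, centring on synonymous variants, the median in place of the mean over a position's substitutions, and no substitutions to proline.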

Results

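The data are scores for the growth of yeast that carried substitutions in a block of 66 residues of the third PDZ domain of PSD-95, a small domain that binds the C-terminal ends of other proteins. The domain was made alone (PDZ3) or with the extensions N, C or both (NC), and each construct was measured in an abundance assay and a binding assay. Each of the 8 sets of construct and assay came from 3 input and 3 output libraries, which the labels describe as biological replicates and the deposited table merges into 1 value. The sets held 34755 (PDZ3), 49212 (N), 53912 (C) and 50748 (NC) variants in abundance and 42836, 48629, 52347 and 52249 in binding. Of the single missense substitutions, 1132 (PDZ3), 1156 (N), 1159 (C) and 1167 (NC) were measured in abundance and 1144, 1171, 1157 and 1175 in binding. The read depth behind them is unknown. The median error of a single substitution ran from 0.0116 (N) to 0.0230 (C) in abundance and from 0.00855 (NC) to 0.0484 (PDZ3) in binding, in units of the deposited score. The median nonsense variant, which ends the protein early, scored -1.17 (PDZ3), -0.901 (N), -1.23 (C) and -1.07 (NC) in abundance and -1.52, -1.48, -1.1 and -0.891 in binding. Values called scaled below are divided by these sizes, so that 0 is the wild type and -1 the median nonsense variant of the same construct and assay. The wild types themselves did not grow alike. Their growth rates, in a time unit not stated, were 0.1475 (PDZ3), 0.147 (N), 0.132 (C) and 0.137 (NC) in abundance. In binding they were 0.134, 0.138, 0.204 and 0.153. Less harmful below therefore means nearer to the construct's own wild type. Positions are in PSD-95 numbering, errors after ± are standard errors (SE) that come from the errors the authors give and, for scaled values, from the spread of the nonsense variants that set the scale, and each position's mean is over 16 to 19 substitutions.

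Nonsense variants at the start of the block were less harmful in the abundance assay than later ones. A stop at R312 had a scaled score of -0.398 in PDZ3, -0.351 in N, -0.640 in C and -0.638 in NC. In binding the same stop scored -1.001, -1.015, -0.9999 and -1.02. Over the first 10 to 12 nonsense variants the abundance medians were -0.536, -0.566, -0.865 and -0.803, against -1.09, -1.07, -1.04 and -1.054 from G345 on (29 to 30 variants), while the binding medians lay between -1.02 and -0.974 at the start. The median over the whole block sets the scale.

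**Figure D1:**
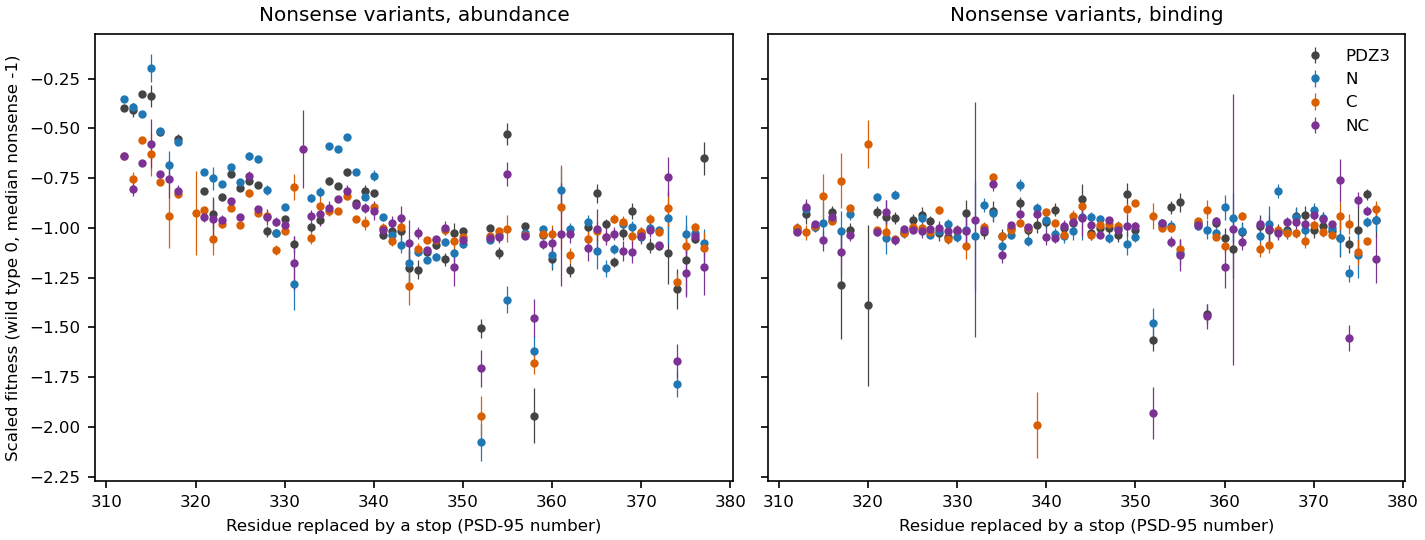
Scaled fitness (vertical axis; wild type 0, median nonsense variant -1) of single nonsense variants by the residue replaced with a stop (horizontal axis, PSD-95 numbering) in the 4 constructs, for abundance and binding, with bars of 1 SE. A stop at R312 stands at -0.398 in the abundance of PDZ3 and at -1.001 in its binding.

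Selection within each construct answers which residues of the domain each construct needs. In the abundance of PDZ3, the mean substitution was most harmful at the glycines G324 (-1.03 ± 0.0297) and G335 (-0.988 ± 0.0289), followed by I359 (-0.931 ± 0.0269), I338 (-0.883 ± 0.0256), L353 (-0.858) and V362 (-0.834). F340 (0.0267), L342 (0.00424), H372 (-0.00610) and T321 (-0.0187) stood at the other end. I359 stayed among the lowest with every extension, at -0.876 in N, -0.803 in C and -0.696 in NC, where F325 came next with -0.417. In N, G324 was lowest (-0.905), and F325 had -0.806, L353 -0.718, I338 -0.704 and V362 -0.700. In C, F325 (-0.6465), I338 (-0.635), V362 (-0.5555), L353 (-0.5545) and G324 (-0.525) followed I359. In NC these were V362 (-0.378), I338 (-0.362), L353 (-0.322) and D357 (-0.313). Substitutions of R368 lay above the wild type, with means of 0.00961 in N, 0.1365 ± 0.00604 in C and 0.150 ± 0.00623 in NC, and 18 of 19 of them passed the test in C and in NC. The other high positions were F340, L342 and H372 in N, F340, L342 and Q374 in C, and R313, V365 and L342 in NC, all between 0.00111 and 0.0521.

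In the binding of PDZ3, G324 of the carboxylate-binding loop was again lowest (-0.972 ± 0.0269), with I359 (-0.890), G329 (-0.887), I327 (-0.880), A375 (-0.880) and I336 (-0.873) close to it. G322 of the same loop was highest, at 0.0679 ± 0.0297, ahead of T321 (0.000137), I377 (-0.00893) and N369 (-0.0373). The lowest positions in N were G324 (-0.947), I327 (-0.863), I359 (-0.840), G329 (-0.814), I336 (-0.785) and A375 (-0.757). In C they were G329 (-0.906 ± 0.00914), I327 (-0.815), H372 (-0.765), G324 (-0.750), I359 (-0.713) and A375 (-0.673), and in NC I327 (-0.771 ± 0.00854), G329 (-0.759), H372 (-0.653), I359 (-0.587), G324 (-0.5685) and A375 (-0.476). G322 was the highest position in each construct, with 0.156 ± 0.0190 in N, 0.0730 in C and 0.0510 in NC. Next to it stood G333 (0.04525), I377 and T321 in N, G333, T321 and E334 in C, and R313 (0.0416), H317 and N369 in NC. The mean of G333 in N includes G333C, at 0.984 units of score, whose difference from PDZ3 has an error of 0.472. The rank of G333 in N may rest on that substitution.

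By the test against the wild type, 927 substitutions passed in the abundance of PDZ3 (843 lower, 84 higher), 911 in N (791 and 120), 675 in C (603 and 72) and 574 in NC (469 and 105). In binding 923 passed in PDZ3 (874 lower, 49 higher), 886 in N (799 and 87), 893 in C (725 and 168) and 833 in NC (672 and 161). Synonymous variants passed as well, mostly above the wild type: 45 of 173 above and 9 below in the abundance of PDZ3, and 38 of 254 above and 4 below in the binding of C. Substitutions above the wild type are the less certain part: with errors multiplied by 2 they numbered 37 (PDZ3), 63 (N), 33 (C) and 47 (NC) in abundance and 9, 28, 92 and 52 in binding, while 290 were lower in the abundance of NC. Centred on the synonymous variants, counts below the wild type were larger in all 8 sets (936 in the binding of C and 915 in the abundance of PDZ3) and those above it smaller (47 and 39).

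**Figure D2:**
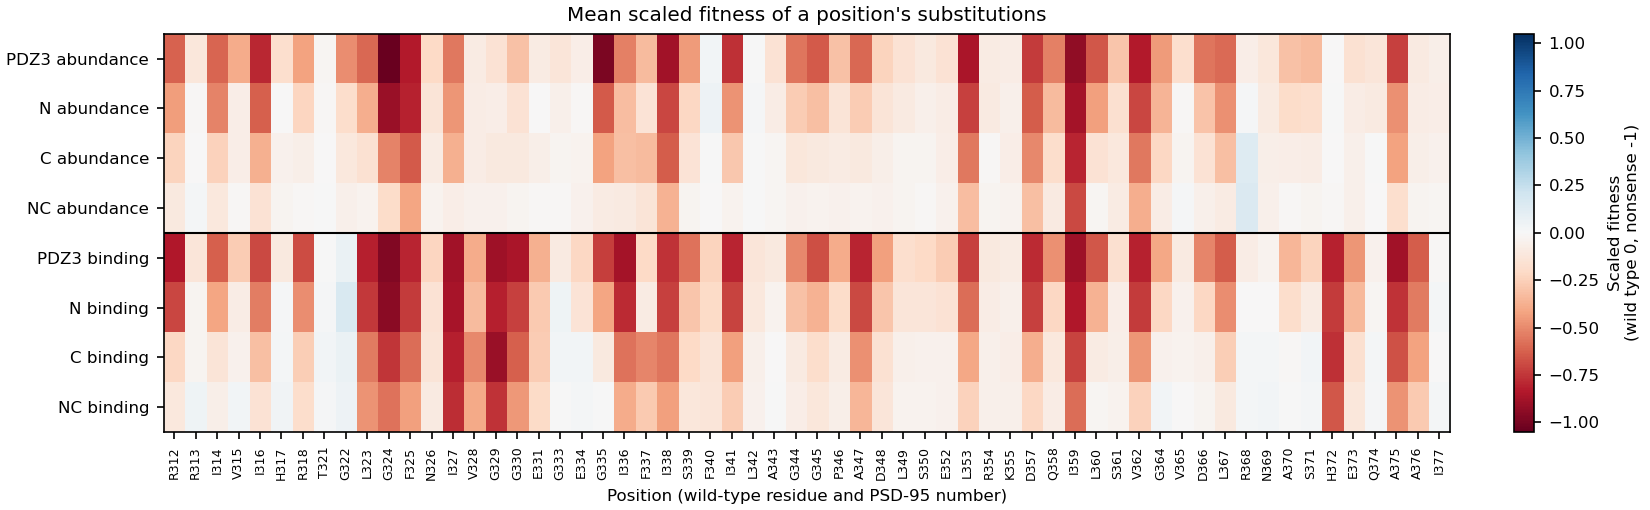
Mean scaled fitness (colour; wild type 0, median nonsense variant -1) of the substitutions at each of 60 positions (horizontal axis, PSD-95 numbering) in the 4 constructs, for abundance (upper block) and binding (lower block). G324 is dark in the PDZ3 lines (-1.03 in abundance, -0.972 in binding), I359 stays dark in the abundance of NC (-0.696), and H372 is pale in the abundance of PDZ3 (-0.00610) and dark in its binding (-0.805).

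The contrasts between constructs ask how the extensions change the effects of substitutions in the domain they are attached to. In abundance, substitutions were less harmful with each extension: the mean over 1128 missense substitutions was -0.389 ± 0.0114 in PDZ3, -0.260 ± 0.0120 in N, -0.175 ± 0.00415 in C and -0.0815 ± 0.00328 in NC. The share of substitutions with a scaled score below -0.5 was 33.7% in PDZ3, 19.4% in N, 12.8% in C and 5.50% in NC. Substitutions to proline stayed the most harmful class, with means of -0.694, -0.533, -0.422 and -0.286 (59 substitutions; PDZ3, N, C and NC), and those to aliphatic or aromatic residues went from -0.361 to -0.216, -0.124 and -0.0398 (508 substitutions). Those to charged residues went from -0.422 to -0.144 in NC (223 substitutions), those to polar residues from -0.343 to -0.0651 (287) and those to glycine from -0.433 to -0.0817 (51). All 5 classes were higher in N, in C and in NC than in PDZ3. The mean rose by 0.130 ± 0.0166 in N (two-sided normal test, p = 4.33e-15, n = 1128 substitutions), by 0.214 ± 0.0122 in C and by 0.308 ± 0.0119 in NC. Without scaling the rise in N was 0.221 units of score.

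**Figure D3:**
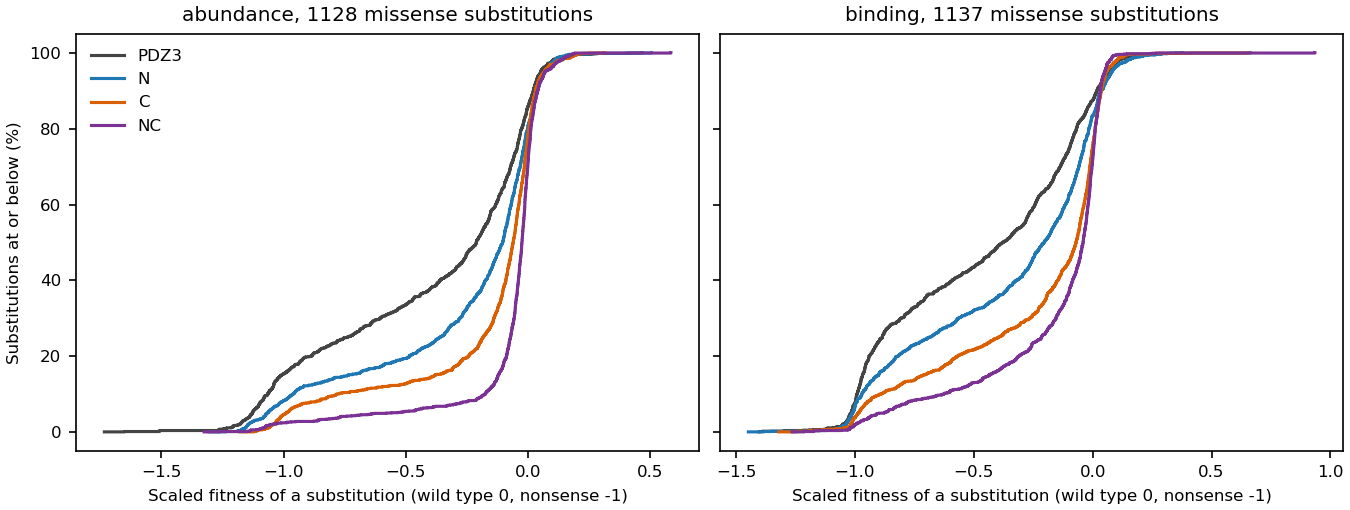
Share of single missense substitutions (vertical axis, cumulative percent) at or below each scaled fitness (horizontal axis; wild type 0, median nonsense variant -1) in the 4 constructs, for abundance (1128 substitutions) and binding (1137 substitutions). At -0.5 the abundance curves stand at 33.7% in PDZ3 and 5.50% in NC, and the binding curves at 43.5% and 13.0%.

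With N, substitutions had higher scaled scores in abundance at 50 of 60 positions and lower ones at none. The largest rises were at G335 (from -0.988 to -0.645, a difference of 0.343 ± 0.0412), A347 (0.331 ± 0.0215), G345 (0.327 ± 0.0243), V315 (0.312 ± 0.0428), I341 (0.300 ± 0.0310) and G322 (0.300 ± 0.0374). Among the positions named beforehand, L323 rose by 0.218, S339 by 0.2305, G330 by 0.157, L353 by 0.139, V362 by 0.134 and I327 by 0.0936. F325 (0.0275), A376 (0.0108) and H372 (0.00721) did not pass. Strand 2, which forms 1 side of the peptide groove, rose less than random lists, with a median of 0.0780 against 0.137 (percentile 2.07): N326 (0.0745), I327, G329 (0.0815) and G330 rose, while F325 and V328 (0.00421) did not pass. Adjusted over the list alone, 4 of its 6 positions passed as well. It was the 1 call among 14 lists, with no adjustment over lists. In simulated data with strand 1 shifted, 7.69% to 15.4% of the other lists lay outside the central range in a contrast. Some of those lists share positions with strand 1, so the rate of calls among unchanged lists is not known. A single call, here, in the abundance of C or in the binding of N, is therefore weak evidence. Of 1128 substitutions, 746 scored higher and 41 lower in N. With errors multiplied by 2 these were 579 and 14, and with errors widened to the spread of nonsense variants from G345 on 470 and 2. Scaled to nonsense variants they were 571 and 46. The largest rises in score were at V315G (1.37 ± 0.550), I338M (1.28 ± 0.0621, from -2.03), R312W (1.054 ± 0.0321) and H317C (1.054 ± 0.4765), and the largest falls at G333D (-0.5355 ± 0.0925), F340Y (-0.435 ± 0.0765), Q358K (-0.304) and L342Q (-0.2501). These falls start from PDZ3 scores above the wild type (0.545, 0.481, 0.3315 and 0.298) and end near it in N (0.00948 to 0.0483), so none became harmful. In PDZ3, I338M (-2.03), V315G (-1.76), R312W (-1.77) and R318W (-1.76) scored below the median nonsense variant (-1.17) and the median of the lowest 5% of missense substitutions (-1.37), so part of their rises with N, C and NC lies outside the range from nonsense to wild type. The call on strand 2 was lost without scaling (percentile 6.31), with the median over substitutions (3.075), with the scale set by the lowest 5% of missense substitutions (2.90) and without variants of high error (27.7).

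With C, the scaled scores in abundance were higher at 51 positions and lower at F340. G335 (0.5615 ± 0.0304), G345 (0.541 ± 0.0201), G324 (0.509 ± 0.0314), A347 (0.497 ± 0.0179), L360 (0.496 ± 0.0268) and I341 (0.486 ± 0.0235) rose most. L323 rose by 0.439, G322 by 0.373, L353 by 0.303, S339 by 0.302, V362 by 0.278, G330 by 0.205, F325 by 0.187, I327 by 0.186 and A376 by 0.0325, while H372 (0.00347) did not pass. All 11 tested positions of the list nearest the N-terminal end rose (11 when adjusted over the list alone), by a median of 0.3625 against 0.226 in random lists (percentile 99.0). Besides G322, L323 and G324 these were R312 (0.383), R313 (0.109), I314 (0.3625), V315 (0.317), I316 (0.419), H317 (0.126), R318 (0.360) and T321 (0.0119). F340 fell by 0.0198 ± 0.00748. Without scaling this fall was 0.0227 units of score. The weighted mean of synonymous variants was 0.0325 in PDZ3 and 0.0109 in C, a gap of like size. Positions were not centred on synonymous variants, so an offset between the wild types could give a fall of this size. Of 1128 substitutions, 666 scored higher and 63 lower in C (507 and 15 with errors multiplied by 2, 468 and 10 with widened errors). I338M (1.60 ± 0.0628), V315G (1.53 ± 0.555), R318W (1.39 ± 0.144) and V315W (1.22 ± 0.116) rose most, and G333D (-0.528), I377Q (-0.346), F340Y (-0.339) and F325Q (-0.318 ± 0.0182) fell most; G333D and F340Y were still at 0.0166 and 0.141 in C, whereas I377Q went from 0.132 to -0.213 and F325Q from -0.962 to -1.28. The fall at F340 did not pass with errors multiplied by 2 (adjusted p = 0.220, n = 19 substitutions) or widened (0.350), and the call on the list nearest the N-terminal end was lost with the median over substitutions (percentile 72.8) and without variants of high error (89.55).

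With both extensions, the scaled scores in abundance were higher at 57 positions and lower at F340, and L342 and H372 were the pair that did not pass (named after their values were seen). G335 went from -0.988 to -0.0825 (0.9055 ± 0.0294), and G324 (0.8445 ± 0.0303), I341 (0.735 ± 0.0228), I316 (0.637), L360 (0.629) and G345 (0.6135) came next. L323 rose by 0.568, A347 by 0.564, L353 by 0.536, I327 by 0.483, V362 by 0.456, G322 by 0.438, S339 by 0.418, F325 by 0.417, G330 by 0.278 and A376 by 0.0632. F340 fell by 0.0294 ± 0.00790, which did not pass with errors multiplied by 2 (adjusted p = 0.0701, n = 19 substitutions) or widened (0.158). Without scaling this fall was 0.0341 units of score. The weighted mean of synonymous variants was 0.0325 in PDZ3 and 0.0199 in NC, so an offset between the wild types could give part of it. None of the 14 lists stood out from random lists. All 5 tested positions of the carboxylate-binding loop rose, as did all 6 of strand 1, all 6 of strand 2, all 5 of helix 1, all 9 of strand 4, 6 of 8 in strand 3, 12 of 13 peptide-contacting sites, all 13 charged, 10 of 11 polar, all 10 glycine or proline and 24 of 26 aliphatic or aromatic positions. In helix 2, 6 of 7 positions rose and 5 passed when adjusted over the list alone. Of 1128 substitutions, 803 scored higher and 49 lower (17 lower with errors multiplied by 2, 5 with widened errors), with I338M (1.99 ± 0.0626, from -2.03 to -0.0352), V315G (1.90 ± 0.552), R318W (1.695 ± 0.143) and G364V (1.36 ± 0.0351) at the top and F340Y (-0.569), G333D (-0.546), Q358H (-0.312) and Q358K (-0.308) at the bottom. Those at the bottom again start above the wild type in PDZ3 (0.481, 0.545, 0.310 and 0.3315) and end near it in NC (-0.0888 to 0.0232).

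**Figure D4:**
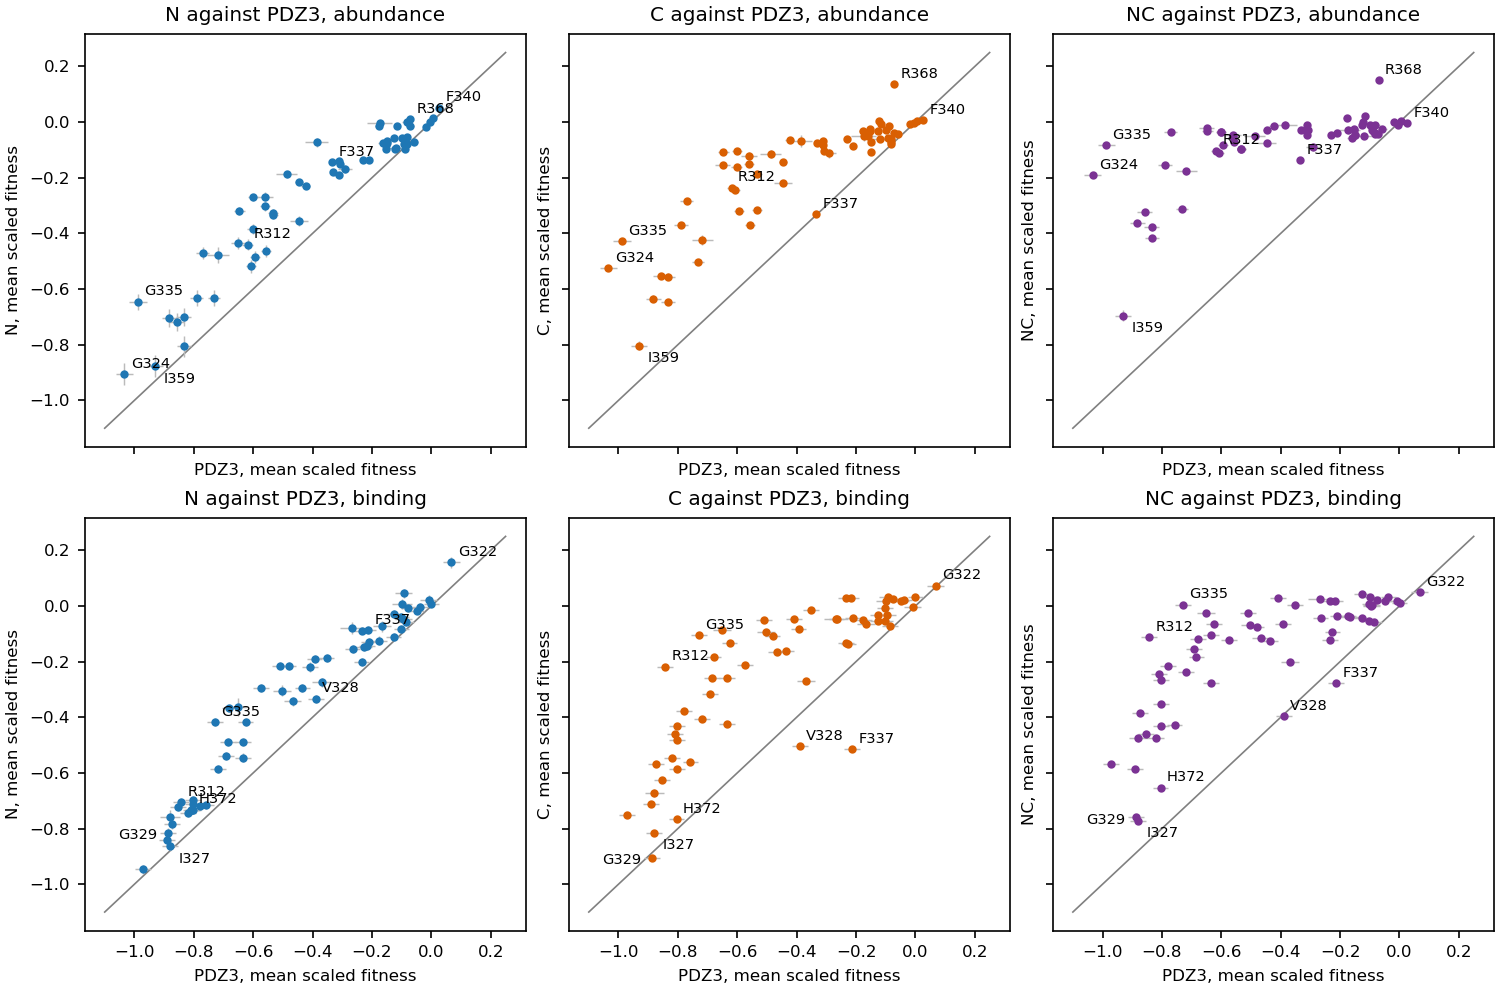
Mean scaled fitness of a position's substitutions in N, C and NC (vertical axes) against that in PDZ3 (horizontal axes), for abundance (upper panels) and binding (lower panels), wild type 0 and median nonsense variant -1, 60 points per panel with bars of 1 SE and the line of equal values. G335 lies far above the line in the abundance of NC (-0.988 against -0.0825), and F337 lies below it in the binding of C (-0.213 against -0.514).

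In binding, substitutions were also less harmful with each extension, with means over 1137 missense substitutions of -0.460 ± 0.0252 in PDZ3, -0.346 ± 0.0132 in N, -0.240 ± 0.00407 in C and -0.168 ± 0.00465 in NC. The share below -0.5 was 43.5%, 32.0%, 21.7% and 13.0%. Substitutions to proline had means of -0.731, -0.633, -0.514 and -0.393 (59 substitutions), those to aliphatic or aromatic residues -0.424, -0.291, -0.179 and -0.120 (513) and those to charged residues -0.4999, -0.4185, -0.328 and -0.253 (226). The means to polar residues went from -0.432 in PDZ3 to -0.143 in NC (288 substitutions) and those to glycine from -0.485 to -0.146 (51), and all 5 classes were higher in N, in C and in NC than in PDZ3. The mean rose by 0.1135 ± 0.0284 in N (two-sided normal test, p = 6.6e-05, n = 1137 substitutions), by 0.220 ± 0.0255 in C and by 0.292 ± 0.0256 in NC. Without scaling the rises were 0.187, 0.438 and 0.552 units of score, and with errors multiplied by 2 no class passed in N.

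With N, substitutions had higher scaled scores in binding at 43 of 60 positions and lower ones at none. All 60 tests share the wild type of PDZ3 (error 0.0379 units of score), so an offset in it would move every position together. G345 (0.3115 ± 0.0302), G335 (0.311 ± 0.0305), D366 (0.2955 ± 0.0298), L360 (0.289 ± 0.0433), S339 (0.280 ± 0.0300) and Q358 (0.264 ± 0.0299) rose most. Strand 1, at the N-terminal end of the domain, rose more than random lists, with a median of 0.145 against 0.0809 (percentile 99.8). All 6 of its positions rose (6 when adjusted over the list alone): R312 by 0.138, R313 by 0.0999, I314 by 0.208, V315 by 0.189, I316 by 0.151 and H317 by 0.1075. In the carboxylate-binding loop 4 of 5 positions rose, R318 (0.195), G322 (0.0883), L323 (0.0764) and F325 (0.0712), and G324 (0.0249) did not pass. G330 (0.133), L353 (0.133), A347 (0.105), A376 (0.0893), V362 (0.0756) and H372 (0.0727) rose as well, and I327 (0.0170) did not pass. Of 1137 substitutions, 510 scored higher and 12 lower (1 lower with errors multiplied by 2, 7 with widened errors), with G333C (1.97 ± 0.472), I314N (1.275 ± 0.0740), L353P (1.16 ± 0.0457) and L360E (1.14 ± 0.126) at the top and D357V (-0.379 ± 0.04475), Q374H (-0.369), L342M (-0.292) and Q374E (-0.2155) at the bottom. Of these, D357V went from -0.921 to -1.3, while Q374H (0.575), L342M (0.239) and Q374E (0.380) lay above the wild type in PDZ3 and at 0.206, -0.0533 and 0.164 in N. The rise of G333C, with its large error, went from -0.990 to 0.984, far past the wild type. In PDZ3, I314N (-2.13), R312M (-2.14), R318W (-2.12), L360E (-1.86) and I338M (-1.82) scored below the median nonsense variant (-1.52), so part of their rises with the extensions lies outside the range from nonsense to wild type. With errors multiplied by 2, 13 positions and 242 substitutions passed, and without variants of high error, which left 3 of its positions, strand 1 was at percentile 67.8.

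With C, the scaled scores in binding were higher at 51 positions and lower at F337 and V328. R312 went from -0.843 to -0.218 (0.625 ± 0.0269) and G335 from -0.728 to -0.104 (0.6245 ± 0.0270), and L360 (0.5655 ± 0.0300), G345 (0.497 ± 0.0271), I314 (0.492 ± 0.0266) and D366 (0.459 ± 0.0266) came next. F337 of strand 3 fell from -0.213 to -0.514, by 0.301 ± 0.0265, and 12 of its 19 substitutions scored lower and 3 higher with C. F337T (-0.6725 ± 0.0433), F337K (-0.666), F337S (-0.6035) and F337R (-0.597) were the largest falls of all substitutions. V328 fell by 0.114 ± 0.0277.

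The peptide-contacting sites changed less in the binding of C than random lists, with a median of 0.102 against 0.272 (percentile 0.180): 9 rose, 1 fell and 3 did not pass, and 10 of 13 passed when adjusted over the list alone. R318 (0.424), S339 (0.363), L323 (0.272), G324 (0.222), F325 (0.216), A376 (0.208), E331 (0.102), N326 (0.0886) and I327 (0.0652) rose and V328 fell, while H372 (0.0397), G322 (0.00514) and G329 (-0.0190) did not pass. For H372 and G329 this depends on the scale: on the unscaled score 18 of 19 substitutions of H372 and all 18 of G329 were higher with C. On that score the median nonsense variant is itself higher with C (-1.1 against -1.52), so substitutions near the nonsense level rise as well. Strand 2 lay at percentile 0.525, with a median of 0.0769 against 0.263: F325, N326, I327 and G330 (0.2295) rose, V328 fell and G329 did not pass (5 of 6 when adjusted over the list alone). Strand 1 lay at percentile 99.3, with a median of 0.298 against 0.160, and all 6 positions rose (6 when adjusted over the list alone): R312, I314, I316 (0.376), V315 (0.220), H317 (0.116) and R313 (0.0955). Of the other lists, 4 of 5 positions rose in the carboxylate-binding loop, 7 of 8 in strand 3 with F337 the exception, 5 of 5 in helix 1, 7 of 9 in strand 4, 5 of 7 in helix 2, 9 of 11 in the list nearest the N-terminal end and 11 of 13 in that nearest the C-terminal end. By residue class these were 23 of 26 aliphatic or aromatic positions with V328 and F337 lower, 11 of 13 charged, 9 of 11 polar and 8 of 10 glycine or proline positions. V362 (0.348), A347 (0.320) and L353 (0.312) also rose. Of 1137 substitutions, 820 were higher and 44 lower on the unscaled score (14 lower with errors multiplied by 2, 34 with widened errors). Scaled to nonsense variants, 683 were higher and 55 lower. On the unscaled score the rises were led by I314N (2.08 ± 0.0691), R312M (1.99 ± 0.0529), L360E (1.825 ± 0.107) and I338M (1.56 ± 0.0534). The fall at V328 was 0.0408 in the other direction without scaling (adjusted p = 0.338, n = 19 substitutions) and did not pass with the median over substitutions (0.0884) or with errors multiplied by 2 (0.0564). The value without scaling carries the limit given for H372 and G329. With the median over substitutions the percentiles of the peptide-contacting sites (5.66) and strand 2 (4.81) were inside the central range, and without variants of high error those of strand 2 (3.445) and strand 1 (86.1, 3 positions) were.

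With both extensions, the scaled scores in binding were higher at 53 positions and lower at F337. G335 went from -0.728 to 0.00448 (0.733 ± 0.0272), R312 went from -0.843 to -0.111 (0.732 ± 0.0270), and L360 (0.627 ± 0.0300), V362 (0.565 ± 0.0277), D357 (0.563 ± 0.0269) and G345 (0.563 ± 0.0272) came next. The peptide-contacting sites again rose less than random lists, by a median of 0.168 against 0.3945 (percentile 0.255), although 11 of 13 rose: R318 (0.499), S339 (0.452), G324 (0.403), F325 (0.371), A376 (0.3555), L323 (0.344), E331 (0.168), H372 (0.152), N326 (0.131), G329 (0.127) and I327 (0.109). G322 (-0.0168) and V328 (-0.00565) did not pass, and 11 passed when adjusted over the list alone. Strand 2 rose by a median of 0.129 against 0.399 (percentile 0.120), with 5 of 6 positions higher (5 when adjusted over the list alone), G330 (0.3945) the most. Strand 1 rose by 0.415 against 0.214 (percentile 99.85), with all 6 positions higher (6 when adjusted over the list alone): R312, I314 (0.560), I316 (0.537), V315 (0.293), R313 (0.169) and H317 (0.132). L353 (0.481) and A347 (0.450) also rose. F337 fell by 0.0638 ± 0.0265. Of 1137 substitutions, 857 were higher and 39 lower on the unscaled score (11 lower with errors multiplied by 2, 39 with widened errors). Scaled to nonsense variants, 770 were higher and 44 lower. On the unscaled score I314N (2.11 ± 0.0689), R312M (2.07 ± 0.0477), L360E (1.83 ± 0.107) and R318W (1.79 ± 0.0707) were at the top. Q374H (-0.529 ± 0.109), G322M (-0.458 ± 0.153), G322A (-0.364) and G322P (-0.348) were at the bottom. All 4 falls start from PDZ3 scores above the wild type (0.575, 0.53, 0.423 and 0.410) and end at 0.0458 to 0.0719 in NC. The value of F337 was 0.07835 without scaling (adjusted p = 0.0512, n = 19 substitutions) and did not pass with errors multiplied by 2 (0.251). On the unscaled score the median nonsense variant is also higher in NC (-0.891) than in PDZ3 (-1.52). Without scaling the peptide-contacting sites (percentile 3.495) and strand 2 (2.605) were inside the central range, as the peptide-contacting sites (4.105) and strand 1 (92.4, 3 positions) were without variants of high error.

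Binding was then set against abundance within each construct, to find residues at which the scaled binding score lies below or above the scaled abundance score. No relation between the scores of the 2 assays was fitted, so a difference need not be a change of binding itself. In PDZ3, binding was far below abundance at H372, the helix 2 histidine that contacts the ligand (-0.805 against -0.00610, a difference of -0.7985 ± 0.0268), and at G329 (-0.732 ± 0.0277), G330 (-0.5455 ± 0.0282), A376 (-0.543 ± 0.0267), I336 (-0.340), I327 (-0.324), V328 (-0.307) and E373 (-0.306). It was above abundance at G322 (0.555 ± 0.0461), G335 (0.260) and L353 (0.138). L323 (-0.218), A347 (-0.201) and S339 (-0.128) were lower in binding, and F325 (0.0310) and V362 (0.0251) did not pass. In N the lowest were G329 (-0.742 ± 0.0170), H372 (-0.733 ± 0.0161), G330 (-0.570), A376 (-0.4645), I336 (-0.458), A347 (-0.426), I327 (-0.4005) and L323 (-0.360), and the highest G322 (0.343), G335 (0.228) and G364 (0.137). In C they were G329 (-0.789 ± 0.0104), H372 (-0.762 ± 0.00882), G330 (-0.521), I327 (-0.445), V328 (-0.424), L323 (-0.385), A347 (-0.378) and A376 (-0.367), against G335 (0.323), G322 (0.1875) and G364 (0.173). In NC they were G329 (-0.711 ± 0.00941), I327 (-0.6985 ± 0.00920), H372 (-0.6435 ± 0.00833), L323 (-0.4415), G330 (-0.429), G324 (-0.379), V328 (-0.354) and A347 (-0.315), against V362 (0.134), I359 (0.109) and G364 (0.104).

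Of 60 positions, binding was below abundance at 22 and above it at 12 in PDZ3, at 25 and 16 in N, at 26 and 26 in C and at 30 and 20 in NC. The division between lower and higher depends on the scale, since without scaling it was 40 and 1 in PDZ3 and 40 and 5 in N, and with the scale set by the lowest 5% of missense substitutions it was 32 and 6 in PDZ3. With errors multiplied by 2, 20 positions passed in PDZ3 (17 lower and 3 higher).

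**Figure D5:**
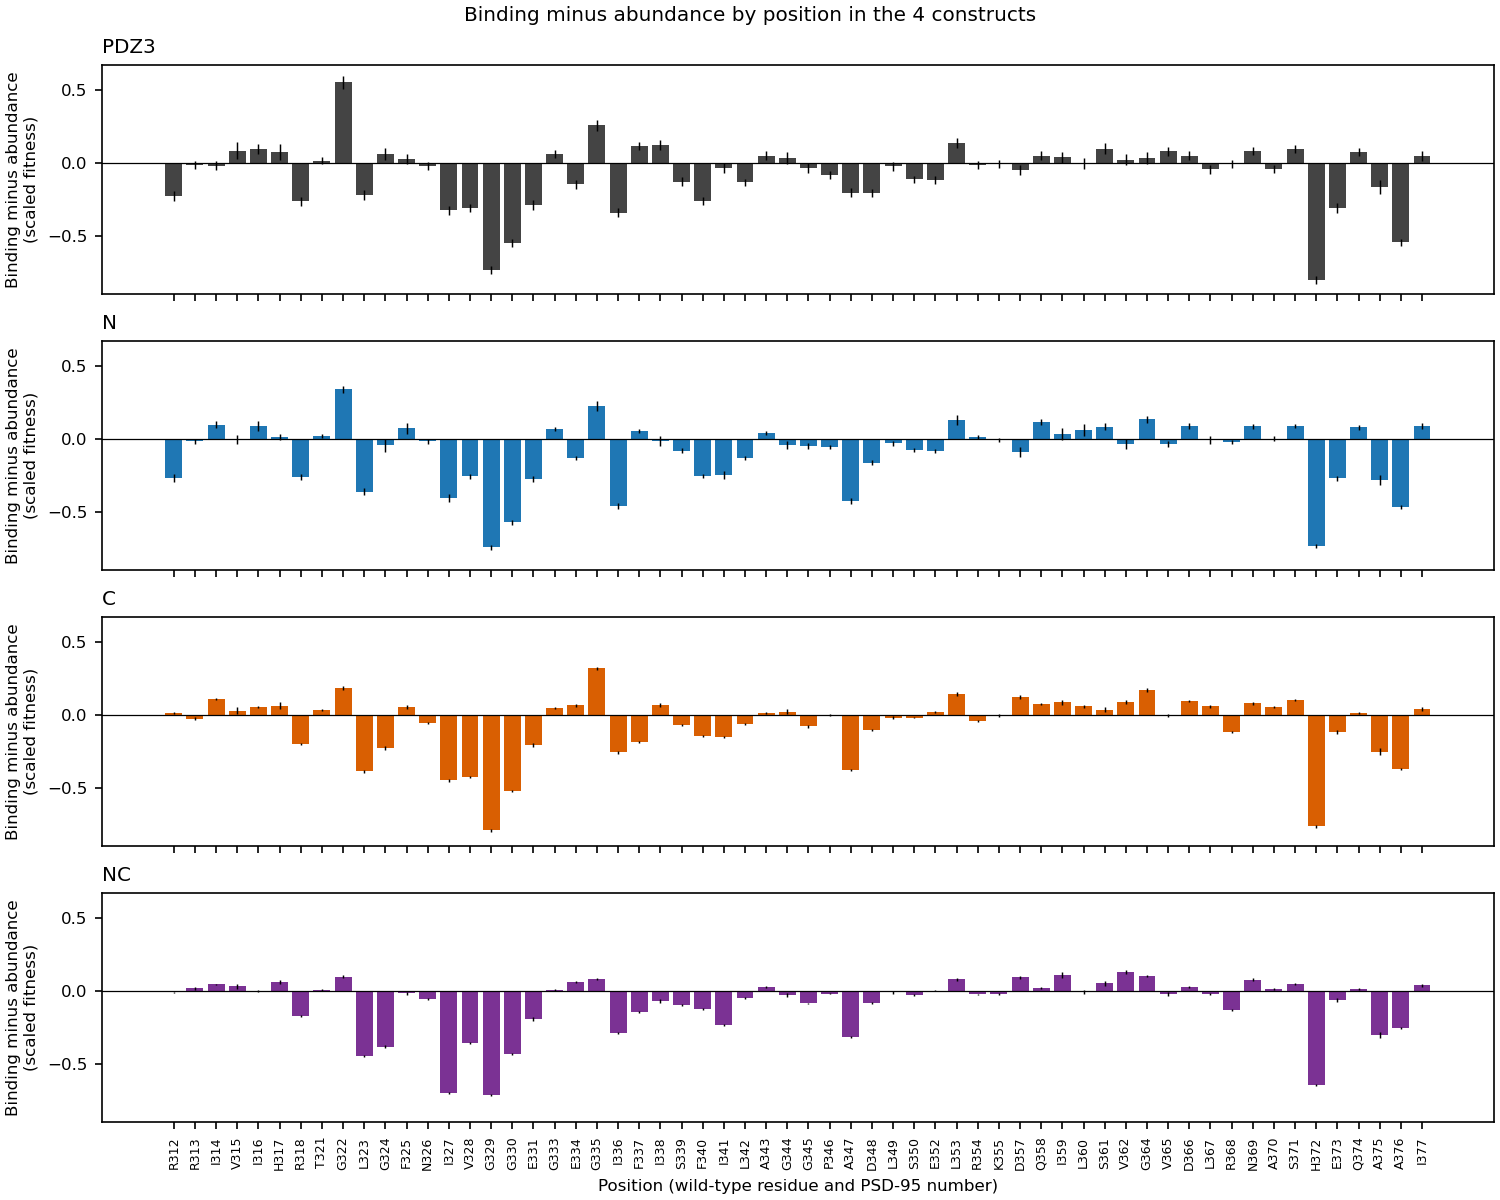
Binding minus abundance of the mean scaled fitness of a position's substitutions (vertical axis, in units in which wild type is 0 and the median nonsense variant -1) at 60 positions (horizontal axis) in the 4 constructs, with error bars of 1 SE. G329 has deep bars in all panels (-0.732 in PDZ3, -0.742 in N, -0.789 in C, -0.711 in NC), and the bar of G322 goes from 0.555 in PDZ3 to 0.188 in C.

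The difference between binding and abundance was then compared between constructs, to ask whether an extension changes the 2 scaled scores unequally. With N it differed from PDZ3 at 7 positions: A347 (-0.225 ± 0.0374), G322 (-0.212 ± 0.0514), I341 (-0.209 ± 0.0439), L323 (-0.142 ± 0.0400), I336 (-0.118) and V365 (-0.113) went down, and I314 (0.119 ± 0.0418) went up. With C it differed at 26, and G322 (-0.368 ± 0.0483), F337 (-0.3045 ± 0.0294), G324 (-0.287 ± 0.0420) and A347 (-0.177) led the 10 that went down, and R312 (0.242 ± 0.0328), E334 (0.212), E373 (0.1905) and A376 (0.176) the 16 that went up. With NC it differed at 29, with G322 (-0.454 ± 0.0478), G324 (-0.441 ± 0.0411), I327 (-0.375 ± 0.0325) and F337 (-0.262 ± 0.0290) first among 13 that went down and A376 (0.292 ± 0.0275), E373 (0.247), R312 (0.217) and E334 (0.206) first among 16 that went up. At G322 binding was already at 0.0679 in PDZ3, so the fall of the difference there comes from the rise in abundance. Without scaling 3 went down and 41 up with C, and 3 and 38 with NC. The count with N depends on the settings and ran from 1 with errors multiplied by 2 to 20 with the median over substitutions, and with errors multiplied by 2 those with C and NC were 10 and 15.

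The 4 constructs also allow the effect of C to be compared with and without N. On the scaled scores it differed between constructs with and without N at 41 positions in abundance, where it was lower with N at 32 and higher at 9. At A347 C raised the scaled score by 0.497 without N and by 0.233 with it, a difference of -0.264 ± 0.0221, and G345 (-0.255 ± 0.0252), V315 (-0.252 ± 0.0496) and G322 (-0.235 ± 0.0410) followed. The effect was higher with N at G324 (0.207 ± 0.0517), I327 (0.204 ± 0.0277), F325 (0.202 ± 0.0466) and L367 (0.126 ± 0.0298). In binding 31 positions differed, 22 with a lower effect of C, led by D366 (-0.271 ± 0.0305), G345 (-0.246 ± 0.0309), Q358 (-0.229 ± 0.0306) and L360 (-0.228 ± 0.0442), and 9 with a higher one, led by G324 (0.157 ± 0.0334), V362 (0.142 ± 0.0332), F337 (0.111 ± 0.0304) and D357 (0.101 ± 0.0313). At F337 the effect of C was negative both without N (-0.301) and with it (-0.190). If both effects simply added up, the score in NC would be that in N plus the effect of C without N. This sum lay above the wild type at 30 of the 32 lower positions in abundance and at 20 of the 22 in binding, from barely (0.00364 at E352 in abundance) to clearly (0.244 at V315 in abundance, 0.2445 at D366 in binding). Among positions that did not pass, it did so at 4 of 19 in abundance and 9 of 29 in binding. The test subtracts this sum from the score in NC, so the 2 are not independent. How far the upper end of the scale accounts for the lower effects was not tested. At the 9 higher positions of each assay the sum lay below the wild type; G324 was near the nonsense level in PDZ3 (-1.03 in abundance), but I327 (-0.556 in abundance) and F337 (-0.213 in binding) were far from it. With errors multiplied by 2, 20 lower and 5 higher positions were left in abundance and 6 and 0 in binding, and with widened errors 14 and 4 in abundance and 16 and 5 in binding. The split also moved with the scale, to 42 and 4 in abundance without scaling and to 30 and 14 with the scale set by the lowest 5% of missense substitutions.

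Across positions, which are not independent replicates, the effect of C without N was related to that with N. Pearson's r was 0.808 in abundance (Spearman's rho 0.856) and 0.827 in binding (rho 0.837), each with the smallest p that the permutations can give (permutation p = 1e-05, adjusted p = 2e-05, n = 60 positions). How far the upper end of the scale affects r was not tested. The effect of N without C was related to that with C in abundance (r = 0.426, permutation p = 0.00073, adjusted p = 0.000973, n = 60 positions; rho 0.621, p = 1e-05). In binding r was 0.0515 (permutation p = 0.698, adjusted p = 0.698, n = 60 positions) and rho 0.187 (p = 0.153). With the median over substitutions the relation for N was not found in abundance either (r = 0.104, permutation p = 0.438, n = 60 positions), and without scaling r was 0.703.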

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

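The tests of F337 without scaling and in the competitions of N and NC were chosen only after the result was seen. The effect of C on a position differed between constructs with and without N at 41 positions in abundance and at 31 in binding, and both counts were singled out because the test of the difference itself passed. At 30 of the 32 lower positions in abundance and 20 of the 22 in binding the score in N plus the effect of C without N would lie above the wild type, and how far the upper end of the scale accounts for them was not tested. The test subtracts this sum from the score in NC, so the 2 are not independent. At the 9 higher positions of each assay this sum would lie below the wild type. With errors multiplied by 2, 5 of these calls were left in abundance and 0 in binding. For the same reason, the difference between binding and abundance stands out where it was unlike that of PDZ3: at 7 positions with N, at 26 with C and at 29 with NC.

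Substitutions of F337 became more harmful with C in binding, from -0.213 to -0.514, while 51 positions rose and V328 alone also fell; the abundance of F337 was -0.334 in PDZ3 and -0.3305 in C. A different growth range of the 2 competitions is argued against by the score without scaling, which also fell by 0.239 ± 0.0396. A few odd substitutions are argued against by the 12 of 19 that passed and were lower. An accident in the competition of 1 construct is argued against by the other pair, in which NC minus N was -0.190 ± 0.0149, although NC against PDZ3 was 0.07835 without scaling. What stays is a hypothesis found and tested on the same data, that F337 may matter more to binding when the domain carries C; how it would do so was not tested.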

How the results depend on the processing

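The tests under alternatives said to be added were chosen only after the result was seen, as were those of lists, classes and means with the scale set by the lowest 5% of missense substitutions or without prolines, and of lists with the median. So was the choice to compare selected substitutions in each direction on its own. Kept means a count within 1.5 times, or for a mean or correlation the same direction and side of the threshold; it does not say that the same lists passed. With centring on synonymous variants 16 of 22 results were kept; counts below the wild type were larger in every set (936 in the binding of C), and those above the wild type were 39 (PDZ3), 51 (N) and 64 (NC) in abundance and 29 (PDZ3), 47 (C) and 77 (NC) in binding. Scaling kept all 6 counts of differing substitutions. In abundance 571 were then higher and 46 lower (N), 680 and 52 (C) and 779 and 48 (NC). In binding these were 470 and 18, 683 and 55, and 770 and 44. The rise of the mean over missense substitutions kept its direction throughout, at 0.104 to 0.221 (N), 0.163 to 0.239 (C) and 0.2497 to 0.367 (NC) in abundance and 0.107 to 0.187, 0.205 to 0.438 and 0.272 to 0.552 in binding. Leaving out variants with an error above the median, which also tests fewer of them, kept 32 of 59 results. Selected substitutions below the wild type were then 450 of 566 (PDZ3), 449 of 578 (N) and 399 of 580 (C) in abundance and 497 of 572, 463 of 586, 411 of 579 and 402 of 588 (NC) in binding, and those above it 53, 66, 42 and 66 in abundance and 23, 40, 93 and 74 in binding. Those differing from PDZ3 were 445 (N), 422 (C) and 487 (NC) of 564 in abundance and 319, 486 and 499 of 569 in binding. Positions differing in the binding of C were 35 of 41, those with binding unlike abundance in NC 31 of 41, and those where this differed with N 4 of 41. Lists outside the central range were 0 in the abundance of C, 1 in the binding of C and 1 in that of NC; the 1 list in the abundance of N was helix 2 in place of strand 2, and that in the binding of N the peptide-contacting sites (lower) in place of strand 1 (higher). With errors multiplied by 2, 31 of 49 results were kept, and the others follow from the wider errors: 290 selected substitutions below the wild type in the abundance of NC, above it 37 (PDZ3), 63 (N), 33 (C) and 47 (NC) in abundance and 9, 28, 92 and 52 in binding, 242 substitutions, 13 positions and 0 classes (1 at an unadjusted p under 0.05 in the normal test) in the binding of N, 25 and 6 non-additive positions in abundance and binding, 20 positions with binding unlike abundance in PDZ3, and 1 (N), 10 (C) and 15 (NC) where this differed. Errors widened to the spread of nonsense variants from G345 on (added) kept 39 of 49 and gave 11 (PDZ3), 21 (N) and 59 (NC) selected substitutions above the wild type in abundance and 46 (N), 52 (C) and 58 (NC) in binding, 472 (N) and 478 (C) differing substitutions and 18 non-additive positions in abundance, and 2 positions where binding against abundance differed with N. For the other settings the cause was not tested. The median over a position's substitutions kept 21 of 25: the correlation of the effect of N was 0.104 in abundance and reversed to -0.141 in binding, 20 positions differed with N in binding against abundance, and no list (0) stood out in the abundance of C; the list in the abundance of N was strand 4 in place of strand 2, and those in the binding of C were strand 1 and strand 4, both higher, in place of strand 1, strand 2 and the peptide-contacting sites. Without scaling 33 of 37 were kept, with the N-terminal list (99.1) called besides the others in the binding of C; 17 (N) and 44 (C) positions differed in binding against abundance, and lists numbered 0 in the abundance of N and 1 in the binding of NC. The scale set by the lowest 5% of missense substitutions kept 36 of 37 and gave 12 positions with N in binding against abundance, and its 1 list in the abundance of N was strand 3, which rose more than random lists, in place of strand 2. The scale set by nonsense variants from G345 on (added) kept 36 of 37 and gave 2 lists in the binding of N, and leaving out prolines kept 36 of 37 and gave 2 in the abundance of N. Another count model, other size factors, count minimums, pseudocounts, a replicate block, wild-type libraries as a filter, an estimated correlation, a fit with only the groups compared and leaving out single cultures were not run, nor could other splits of the samples be counted, because counts and per-culture values are not in the table. The unknown depth limits how far the errors can be judged.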

Other observations

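The test of double substitutions against the wild type, that of a single factor for all positions and the test of nonsense variants in the binding assay were chosen only after the result was seen. Double substitutions, which the comparisons of the report do not use, showed a like order of the constructs. The median double substitution had a scaled score of -0.956 in PDZ3, -0.645 in N, -0.559 in C and -0.172 in NC in abundance, and of -0.967, -0.913, -0.670 and -0.386 in binding. Of them 72.8% lay below -0.5 in the abundance of PDZ3 (30294 measured), 56.6% in N (43167), 52.7% in C (47420) and 29.1% in NC (44865). In binding these were 85.3%, 73.8%, 58.6% and 43.2%. Doubles that passed the test above the wild type made up 0.324% (PDZ3), 0.744% (N), 0.289% (C) and 0.751% (NC) in abundance, less than the 26.0%, 15.6%, 6.64% and 6.25% of synonymous variants that did so. These shares come from unlike tests, adjusted over 30294 to 47420 doubles and over 173 to 286 synonymous variants, so they do not measure gains. The doubles were also not matched between constructs.

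Some residues had substitutions above the wild type, named here after their values were seen. At R368, 9 of 19 substitutions were higher in the abundance of PDZ3, 14 in N, 18 in C and 18 in NC, and its mean rose by 0.207 ± 0.00825 in C and by 0.221 ± 0.00839 in NC. In binding 8 of 19 were higher in N, 15 in C and 13 in NC. Its mean still lay below the wild type in the abundance of PDZ3 (-0.0706 ± 0.00562) and was -0.00682 in the binding of N. At F340, 11 of 19 were higher in the abundance of PDZ3 and 11 in N. At R354, 10 of 19 were higher in the abundance of C and 15 in that of NC, and at L367 12 in NC, although the means of R354 (-0.0140 in C, -0.0323 in NC) and L367 (-0.0829 in NC) lay below the wild type. At R313, 14 of 19 were higher in the binding of NC. At G322, 7 of 19 were higher in the binding of PDZ3, 11 in N, 15 in C and 12 in NC. These counts by residue are not centred on synonymous variants, whose weighted mean was 0.0440 units of score in the binding of C. Centred on them, 47 substitutions in place of 168 lay above the wild type in that set. In the binding of NC 77 in place of 161 did.

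Substitutions were milder with C and NC. A single factor that multiplies the scaled score of all positions is argued against by the binding of C. The slope of C on PDZ3 was 0.681 over the 20 positions lowest in N and 0.284 over the middle 20, a difference of 0.398 ± 0.0641 (0.3975). Some of the lowest lay near the nonsense level in PDZ3 (G324 -0.972, I359 -0.890), where the scale is bounded. The slopes therefore cannot decide on a common change that acts before such a bound. A candidate explanation is spare stability, under which a mild substitution costs more once another has used it up. Harmful here means below -0.5 in the abundance of PDZ3, and intermediate means between -0.5 and -0.1 there. Alone, the harmful partners had means of -0.667 (N), -0.464 (C) and -0.226 (NC), so in NC they were mild on average. The errors draw only the intermediate substitutions, although pairs share harmful partners, and PDZ3 itself was not computed. Substitutions of intermediate effect in PDZ3 lowered abundance in C by -0.0632 alone and by -0.296 on top of a harmful substitution (difference -0.233 ± 0.00838, 9844 pairs), and in NC by -0.0271 and -0.200 (-0.173 ± 0.00860, 9239 pairs). With N, the same difference was -0.0895 ± 0.00866 (8939 pairs). A plateau of the assay at high abundance would give the same values and stays open.

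In the abundance assay, nonsense variants near the start of the block lay above those from G345 on, by 0.552 ± 0.129 in PDZ3, 0.501 ± 0.106 in N, 0.173 ± 0.0674 in C and 0.252 ± 0.0596 in NC. Wild-type reads counted as nonsense would raise them in binding too, where the difference was 0.00432 ± 0.0186 over the 4 constructs. Lower precision near the start is argued against by the errors, which were smaller there, with a ratio of at most 0.646. No biological explanation was tested.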
